A study of Homo sapiens with 16 samples.

How the data were processed

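MicroRNA abundance was measured on 16 single-colour arrays, 2 for each of 8 groups, with RNA from a human breast epithelial line (MCF10A), a human breast carcinoma line (MDA-MB-231) and exosomes released by both. Per the labels, total RNA was extracted with Trizol from cells and from exosomes, both lines were grown in medium whose serum had been depleted of exosomes, and the labelled target was bound by a fluorescent streptavidin conjugate. The labels' protocol names an exon-array labelling kit, whereas the probe names are those of a microRNA array; which description holds was left open. Exosomes were isolated by ultracentrifugation, per the series design text.

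The authors deposited a table of log2 signals for 2997 probes on all 16 arrays, and its values ran from 2.85 to 16.00. The array medians over all probes lay between 7.28 and 7.44, so the values had been normalized between arrays; the method, scanner and background correction are not given in the sources used here. The distributions of the arrays were close but not identical. In all, 35 signals stood at or above 15.99, the top of the scale, and differences that involve them are bounded by it.

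From the probe names, 1741 probes of human microRNAs were tested. Of these, 605 carry the ending -P, read here as probes of the precursor, 21 the ending -AP, and 1115 are mature or other probes; the table itself does not state what the endings mean. The 1084 mouse probes, 93 mismatch probes and 38 Randomer probes, taken as random-sequence controls, were not tested. The 79 probes without a microRNA name, which include the Randomer probes, were used for an alternative centring, and snoRNA and GAPDH probes among them for a check of carried-over RNA. Of the 865 distinct human microRNA names, 837 matched a gene in a RefSeq table of assembly GRCh38.p14, which served for names only, and 28 did not.

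Groups came from the sample labels, as did replicate numbers. No label says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, whose source is not known. Signal over background was taken from the share of the 1115 mature probes above the 95th percentile of the Randomer probes on the same array. It does not show that a probe's own microRNA was present, since mouse probes passed as well, as given below. With 2 arrays per group the number of arrays limits the precision of every value, and an exact permutation test of 2 against 2 cannot give a two-sided p below 0.333.

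Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off) in a single fit of all 16 arrays with 8 residual degrees of freedom and 3.29 prior degrees of freedom. Every adjusted p for a microRNA below is limma's, two-sided, with Benjamini-Hochberg adjustment over the 1741 probes; a probe was called at an adjusted p under 0.05. Differences are log2 differences of group means ± standard error (SE). The SE comes from the single fit, which averages the spread of all 8 groups, so a probe has the same SE in each comparison of 2 groups. Since exosome arrays varied more than cell arrays, this SE tends to be too small between exosomes and too large between cells. The 10 comparisons made include 2 interactions, that is, differences between the lines in a contrast. On simulated data with 200 probes changed, each group's typical spread was given to all its probes. This fit then recovered at least 95.3% of changes of 3 log2 units in each of 7 comparisons simulated, 10 runs each. Its false share of calls reached 37.9% (MCF10A shDicer). Real probes differ in spread, so these values need not hold for the data.

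The comparisons, tests, alternatives, 17 microRNA lists and the rule for naming microRNAs were fixed before the data were examined. The rule chose among called probes whose highest group mean exceeded the median of the tested probes (7.30). In comparisons of 2 groups it also required that the arrays did not overlap between the groups. It took the 10 with the largest positive and the 10 with the largest negative difference, 1 probe per microRNA name. For interactions it took 5 per direction, and overlap was not checked. Where fewer than 5 passed in a direction, those with the smallest p were added as not past the threshold. Members of the list named by the study and 2 to 4 examples of each list described were added. Of the probes so named, those whose calls rest on a particular array are mostly given as counts.

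The lists held 6 microRNAs that the study behind these samples named as carried by cancer exosomes, the epithelial miR-200 group, the let-7 family, the miR-17-92 cluster and its paralogues, the miR-15/16 family, the miR-23/27/24 clusters, the miR-29 and miR-30 families, microRNAs reported to favour invasion in breast cancer, microRNAs reported to restrain tumours, microRNAs often reported in extracellular vesicles, and microRNAs that bypass Drosha. Markers of other sources were blood and serum, brain, muscle and pluripotent stem cell microRNAs, the placental cluster on chromosome 19 and the imprinted cluster at 14q32. A member's value was that of its own mature probe, the brightest where there were several; a wider reading that takes any arm or the precursor was an added alternative. Of the members fixed, miR-30e, miR-31 and miR-208b were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 170 tests (17 lists in 10 comparisons), and again with an estimated correlation. List counts "adjusted over the list alone" use the members' p-values only.

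Results were also computed with quantile normalization, median centring on the probes without a microRNA name, a filter that kept probes brighter than the median, the arrays of the compared groups only, the replicate number as a block, eBayes with trend and robust on, and leaving out each array in turn. A fit with an array left out assumes that the lone array of its group varies like the other groups. After the replicate spread had been seen, 2 fits were added: array weights (limma's arrayWeights), and fits restricted to the 10 exosome arrays (5 residual degrees of freedom) or to the 6 cell arrays (3 residual degrees of freedom), called fits of the same sample kind. For the precursor probes the estimated correlation was likewise added later. DICER1 is not measured by a microRNA array, so the knockdown could not be checked here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.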

Results

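The data comprised microRNA signals of MCF10A cells, a non-tumorigenic breast epithelial line, MDA-MB-231 cells, an invasive breast carcinoma line, MCF10A cells given MDA-MB-231 exosomes, and exosomes in 5 groups. Exosomes, small vesicles that cells release, came from MCF10A, from MDA-MB-231, from both lines with Dicer knocked down (shDicer), and from MDA-MB-231 with an antibody to Dicer inside them. Dicer is the enzyme that cuts precursor microRNAs into mature ones. Each of the 8 groups had 2 arrays. Replicate arrays of cells correlated at r = 0.970 to 0.982 over the tested probes, and those of exosomes at 0.770 to 0.909. The replicate SD, the SD over probes of the difference between both arrays scaled to a single array, was 0.258 to 0.340 log2 units in the cell groups and 0.588 to 0.905 in the exosome groups. Between 34.3% and 44.8% of mature probes lay above the random-sequence probes on cell arrays, against 16.3% to 38.3% on exosome arrays. For most of the named microRNAs in exosome comparisons the lower group lay within the range of the random-sequence probes (18 of 20 between the exosomes of the lines, for example), so the size of those differences is bounded by background.

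The central comparison set exosomes of carcinoma cells against those of non-tumorigenic cells. On the MCF10A exosome arrays 16.3% and 18.7% of mature probes lay above the random-sequence probes, against 31.2% and 25.3% on the MDA-MB-231 exosome arrays. The larger number of probes higher in MDA-MB-231 exosomes goes with that difference, whose part in it was not tested. miR-615-3p, encoded within the HOXC cluster, was 5.24 ± 0.31 log2 units higher in MDA-MB-231 exosomes (11.69 against 6.46, n = 2 arrays each, adjusted p = 4.6e-06). miR-1260b rose by 3.98 ± 0.28 (adjusted p = 1.17e-05) and miR-1308 by 5.85 ± 0.48 (adjusted p = 3.38e-05). miR-1246, often found in extracellular vesicles, was lower in MDA-MB-231 exosomes by -2.78 ± 0.27 (11.43 against 14.20, adjusted p = 8.68e-05), and the probe of the miR-204 precursor by -3.53 ± 0.49 (adjusted p = 0.00107). Other large differences were miR-4301 at 5.17 ± 0.52, miR-1979 at 4.47 ± 0.42 and miR-4324 at 3.86 ± 0.33. miR-1308 and miR-1979, like miR-1274b and miR-923 below, have no gene of that name in the RefSeq table. Such names made up 22 of the 130 calls in this comparison (16.9%, against 3.1% of all probes tested). In the let-7 family, which restrains growth, 1 of 9 members rose, let-7a by 1.52 ± 0.30 (adjusted p = 0.0112). None of the 6 microRNAs that the study named as carried by cancer exosomes passed the test over all probes, and 5 of the 6 were lower in MDA-MB-231 exosomes. miR-10b, reported to favour invasion, differed by -2.60 ± 0.79 (adjusted p = 0.0727) and miR-10a by -0.82 ± 0.33 (adjusted p = 0.183). For miR-10b the MCF10A exosome arrays spread more widely than this SE conveys, as given below. miR-27a differed by -0.84, miR-21 by -0.68, miR-155 by -0.51 and miR-373 by 0.07. Adjusted over the list alone, 1 of the 6 fell. This is not taken as independent evidence, because the study behind these samples named these microRNAs and how it chose them is not known here. The list as a whole had an adjusted p of 0.119 in camera. No list was called between the exosomes of the lines.

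Of 1741 probes, 130 were called in limma, 98 higher and 32 lower in MDA-MB-231 exosomes. In a fit of the exosome arrays alone 31 of these were called (29 higher and 2 lower, mir-204-P and miR-1246), and with only the 4 arrays compared limma called 0, against 169 at an unadjusted p under 0.05. All the microRNAs given above with a rise of 3 log2 units or more kept their calls in the exosome fit, whereas let-7a did not. The count was 240 without replicate 1 of the MCF10A exosomes, 65 without replicate 1 of the MDA-MB-231 exosomes and 61 without their replicate 2; the higher share of calls, 75.4%, became 86% after centring and 65.9% after quantile normalization.

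**Figure D1:**
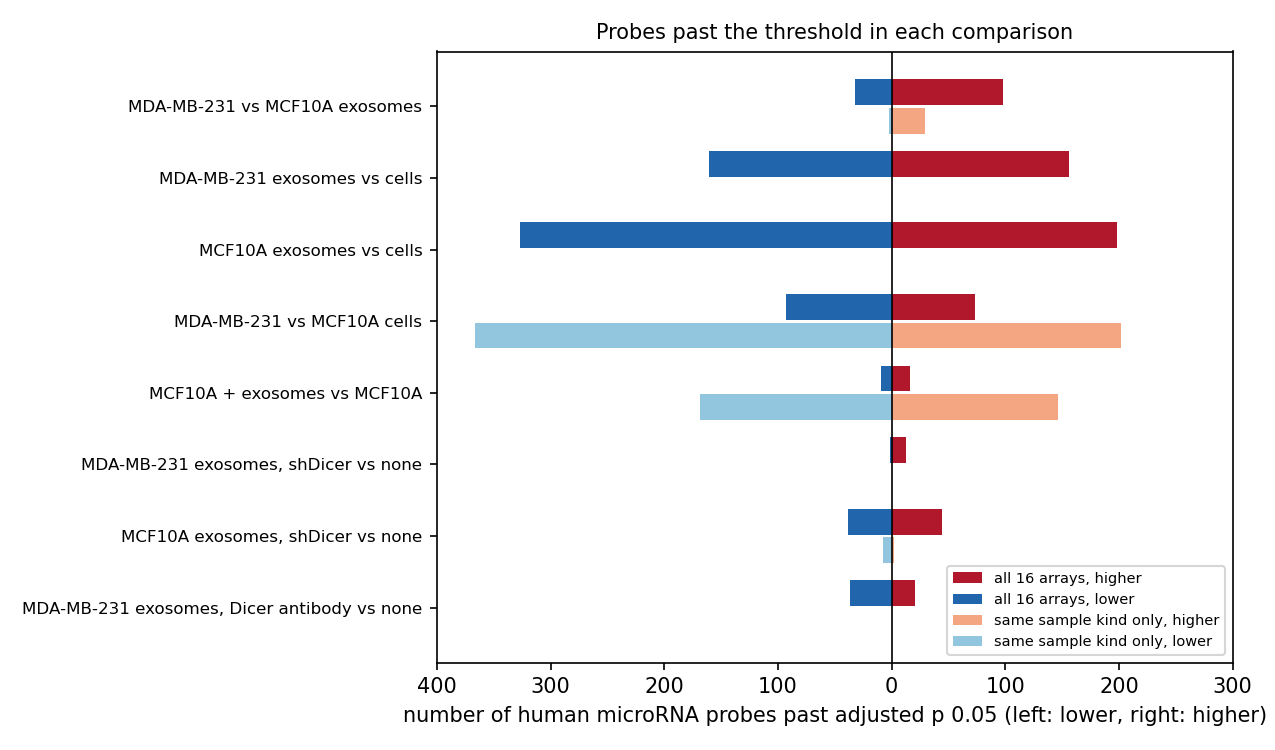
Number of human microRNA probes called at an adjusted p under 0.05 in 8 comparisons, with higher probes to the right and lower probes to the left of 0; dark bars are the fit of all 16 arrays and light bars the fit of the same sample kind, which does not apply to the exosome-cell comparisons and gave 0 for MDA-MB-231 shDicer and for the Dicer antibody. Counts for exosomes of the lines were 130 and 31, and those for the cell lines 166 and 569.

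Exosomes were next set against the cells that made them, the control profile of the series. In MDA-MB-231, miR-30b was lower in exosomes by -5.16 ± 0.53 (6.79 against 11.94, n = 2 arrays each, adjusted p = 0.000133). miR-20a and miR-17, members of the growth-promoting miR-17-92 cluster, were lower by -4.82 ± 0.52 (adjusted p = 0.000161) and -4.44 ± 0.54 (adjusted p = 0.000274). miR-222 was lower by -4.30 ± 0.44, and miR-21, an abundant microRNA of many tumours, by -4.07 ± 0.50 (adjusted p = 0.000274). The probe of miR-17 exceeded all its mismatch probes on 0 of 6 cell arrays and that of miR-222 on 2 of 6, against 4 of 6 for miR-21, so signal at the first pair is not shown to be specific. Among mature probes 130 fell and 101 rose. miR-466 was higher in exosomes by 3.92 ± 0.27 (adjusted p = 6.85e-06), miR-338-3p by 3.20 ± 0.54 (adjusted p = 0.00188), miR-760 by 2.75 ± 0.27 and miR-548j by 2.50 ± 0.27. Probes of the precursors of miR-4256 and miR-3149 were higher by 4.60 ± 0.29 and 4.33 ± 0.29.

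In the miR-17-92 list, 8 of 13 measured members fell and none rose (9 fell adjusted over the list alone), and the list was lower with an adjusted p of 3.27e-06 and of 0.0139 with an estimated correlation. miR-20b at -4.48 ± 0.50 and miR-25 at -3.18 ± 0.37 were among them. Several members of this list have similar sequences, so here and in the other family lists the members need not be separate measurements. In the let-7 family 6 of 9 members fell, and 6 adjusted over the list alone. let-7a was lower by -3.82 ± 0.30, let-7c by -3.23 ± 0.35 and let-7b by -2.33 ± 0.26. The list had an adjusted p of 4.21e-05, and adjusted p = 0.112 with an estimated correlation. In the miR-23/27/24 list 4 of 5 fell, and 4 adjusted over the list alone, with miR-24 at -2.93 ± 0.39 and miR-27b at -2.19 ± 0.38 (list adjusted p = 0.00221; adjusted p = 0.0661 with an estimated correlation). Of 7 miR-29 and miR-30 members 4 fell, all of the miR-30 family, with miR-30d at -3.05 ± 0.28; adjusted over the list alone 1 rose and 4 fell (list adjusted p = 0.00643; adjusted p = 0.113 with an estimated correlation). Of 10 microRNAs linked to invasion 4 fell, and 5 adjusted over the list alone, among them miR-221 at -3.25 ± 0.37 and miR-107 at -2.85 ± 0.44 (list adjusted p = 0.000688; adjusted p = 0.0582 with an estimated correlation). Of the study's 6 microRNAs 1 fell, miR-21, over all probes and also adjusted over the list alone, which is not independent evidence; miR-10b differed by -1.05, miR-27a by -1.24, miR-155 by -0.61, miR-10a by -0.11 and miR-373 by 0.52, and the list's adjusted p was 0.196.

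Calls of miR-106b, miR-23a, miR-23b and miR-30a, counted above, were lost on leaving out any of the 4 arrays, with the largest adjusted p 0.0919 (without replicate 2 of the cells), 0.133, 0.107 (both without replicate 1 of the cells) and 0.103 (without replicate 2 of the cells). For let-7e it was 0.118 and 0.0827 without replicate 1 or 2 of the cells and 0.12 without replicate 1 of the exosomes, and for miR-30c 0.0554 without replicate 2 of the cells and 0.0575 without replicate 2 of the exosomes. In total 317 probes were called for MDA-MB-231, 156 higher and 161 lower in exosomes. Without replicate 1 of the MDA-MB-231 cells 137 were called and without their replicate 2, 155; the higher share moved from 49.2% to 37.4% with centring, which shifted the median of all probes by -0.19, and to 56.4% with quantile normalization.

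The same comparison was made in MCF10A. miR-206, a muscle microRNA, was lower in exosomes by -5.06 ± 0.34 (7.76 against 12.82, n = 2 arrays each, adjusted p = 2.62e-06), miR-1274b by -5.60 ± 0.39 (adjusted p = 2.62e-06) and miR-595 by -5.01 ± 0.53 (adjusted p = 3e-05). The precursor probes of miR-566 and miR-1273d were lower by -5.81 ± 0.34 and -6.02 ± 0.54. miR-466 was higher, at 14.85 against 9.86 (adjusted p = 1.34e-06), miR-1289 was higher by 3.52 ± 0.34 and miR-548j by 3.46 ± 0.27. The passenger strand let-7a* was higher by 3.46 ± 0.31 whereas let-7a was lower, by -2.48 ± 0.30. Of its family let-7b (-2.28), let-7c (-1.98), let-7e (-4.56) and let-7i (-1.62) were also called lower, as in MDA-MB-231. let-7g was called higher by 1.05 ± 0.34, while let-7d, let-7f and miR-98 were not called, and the let-7 list was not called here. Precursor probes of miR-3149 and miR-4256 were higher by 4.86 ± 0.29 and 4.75 ± 0.29. In the miR-29 and miR-30 list, which was not called here, 2 of 7 members rose and 1 fell, among them miR-29a, which represses collagens, at 3.43 ± 0.28 (adjusted p = 6.55e-06).

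In the miR-23/27/24 list 2 of 5 members rose, miR-23a by 2.95 ± 0.27 and miR-23b by 1.86 ± 0.26, and 4 rose adjusted over the list alone; the list was higher with an adjusted p of 0.013, and adjusted p = 0.112 with an estimated correlation. Of the study's 6 microRNAs 2 rose over all probes, and 2 adjusted over the list alone, which is not independent evidence: miR-10a by 1.76 ± 0.33 (adjusted p = 0.00172) and miR-10b by 3.06 ± 0.79 (adjusted p = 0.0116). The arrays behind the miR-10b mean of 10.02 in exosomes had an SD of 2.36, and its adjusted p was 0.0726 without replicate 1 of the MCF10A cells and 0.0532 without their replicate 2. miR-27a differed by 1.84 (adjusted p = 0.0902), miR-155 by 0.27, miR-21 by 0.19 and miR-373 by -0.01, and the list's adjusted p was 0.182. In total 525 probes were called, 198 higher and 327 lower, against 317 in MDA-MB-231; with array weights the counts were 421 and 470, and with only the groups compared 392 and 386. The higher share in MCF10A, 37.7%, was 29.1% with centring and 47.5% with quantile normalization. Quantile normalization moved the median difference of all probes from -0.08 to 0.13, and centring shifted it by -0.20.

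Probes called in both lines numbered 95 higher in exosomes, against 17.7 for independent lists, and 96 lower, against 30.2. The comparisons share no array, but their calls come from 1 fit with a common spread per probe. The counts for independent lists are therefore not a fair reference. The difference between exosomes and cells was itself compared between the lines. miR-125b, the human counterpart of lin-4, had an exosome-cell difference lower in MDA-MB-231 than in MCF10A by -4.73 ± 0.40 (n = 2 arrays in each of 4 groups, adjusted p = 8.95e-05), miR-106a by -4.35 ± 0.68 (adjusted p = 0.00231) and miR-21 by -4.26 ± 0.70 (adjusted p = 0.0031). The precursor probes of miR-1273d and miR-566 had a difference higher in MDA-MB-231 by 8.55 ± 0.77 and 6.47 ± 0.48. In the miR-17-92 list 7 of 13 members were lower in this contrast, and 7 adjusted over the list alone (list adjusted p = 1.6e-07, and 0.0102 with an estimated correlation). In the miR-23/27/24 list 4 of 5 were lower, and 5 adjusted over the list alone, with miR-23a at -4.02 ± 0.39 and miR-24 at -4.02 ± 0.55 (list adjusted p = 4.61e-07, and 0.0135 with an estimated correlation). Of the miR-29 and miR-30 members 5 of 7 were lower, and 7 adjusted over the list alone, with miR-29a at -2.73 ± 0.40 (list adjusted p = 3.4e-06, and 0.0234 with an estimated correlation). Of the microRNAs linked to invasion 5 of 10 were lower, and 6 adjusted over the list alone, with miR-221 at -3.61 ± 0.52 and miR-107 at -3.49 ± 0.62 (list adjusted p = 1.61e-05, and 0.0234 with an estimated correlation). This contrast equals the difference between the exosomes of the lines minus that between their cells. In these lists the exosome part was small, with medians of -0.37, -0.76, 0.52 and -0.34 between exosomes in the order given, against 2.35, 3.26, 3.31 and 1.95 between cells, so the list results mostly restate the difference between the cell lines given below.

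Of the members counted here, miR-29b, miR-30a and miR-30d lost their calls together without replicate 2 of the MCF10A cells (adjusted p = 0.0834, 0.0969 and 0.0733), which left 2 of 7. miR-29b and miR-30a lost theirs without 6 of the 8 arrays, with the largest adjusted p 0.146 (without replicate 1 of the MCF10A cells) and 0.113 (without replicate 2 of the MDA-MB-231 cells). miR-30d also lost its call without replicate 1 or 2 of the MDA-MB-231 cells (0.0716 and 0.0531). miR-106b lost its call in all fits but that without replicate 2 of the MCF10A exosomes, with adjusted p up to 0.111, and miR-92a without replicate 1 of the MCF10A cells (0.0566) or of the MDA-MB-231 cells (0.053).

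The study's list had 3 of 6 members lower in this contrast between the lines, and 4 adjusted over the list alone, which is not independent evidence (list adjusted p = 0.00249; adjusted p = 0.103 with an estimated correlation). Besides miR-21 these were miR-10a at -1.87 ± 0.47 (adjusted p = 0.0266) and miR-10b at -4.11 ± 1.12 (adjusted p = 0.0374). For miR-10a the adjusted p was 0.0577 and 0.11 without replicate 1 or 2 of the MCF10A cells, 0.0815 and 0.0992 without replicate 1 or 2 of the MDA-MB-231 cells, and 0.0909 without replicate 2 of the MDA-MB-231 exosomes. For miR-10b it was 0.125 and 0.106 without replicate 1 or 2 of the MCF10A cells, 0.102 and 0.123 without replicate 1 or 2 of the MDA-MB-231 cells, and 0.111 and 0.0649 without replicate 1 or 2 of the MDA-MB-231 exosomes. miR-27a differed by -3.08 ± 1.07 (adjusted p = 0.0981), miR-155 by -0.88 and miR-373 by 0.53. The contrast called 176 probes, 122 higher and 54 lower. The count was 101 and 103 without replicate 1 or 2 of the MCF10A cells, 88 and 101 without replicate 1 or 2 of the MDA-MB-231 cells, and 267 without replicate 1 of the MCF10A exosomes.

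Between the cells themselves, miR-125b was 5.87 ± 0.28 higher in MDA-MB-231 (14.30 against 8.43, n = 2 arrays each, adjusted p = 2.05e-07), miR-130a 6.01 ± 0.46 higher (adjusted p = 8.14e-06) and miR-23a 4.15 ± 0.27 higher (adjusted p = 2.72e-06). miR-99b rose by 5.08 ± 0.87 and miR-25 by 4.47 ± 0.37. miR-21 was higher by 3.58 ± 0.50 (adjusted p = 0.000619). miR-1246 was lower in MDA-MB-231 cells by -5.80 ± 0.27 (9.99 against 15.79, adjusted p = 2.05e-07), miR-1290 by -4.16 ± 0.33 and miR-3117 by -4.08 ± 0.37. miR-4324 was higher by 5.18 ± 0.33, whereas its precursor probe was lower.

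Of the 7 miR-29 and miR-30 members 6 rose in MDA-MB-231 cells, and 7 adjusted over the list alone, with miR-30d at 3.33 ± 0.28 and miR-29a at 2.25 ± 0.28 (list adjusted p = 6.35e-10, and 0.0102 with an estimated correlation). In the miR-23/27/24 list 4 of 5 rose, and 5 adjusted over the list alone, with miR-23b at 3.33 ± 0.26 and miR-24 at 3.26 ± 0.39 (list adjusted p = 7.74e-09, and 0.0102 with an estimated correlation). In the miR-17-92 list 7 of 13 rose, and 8 adjusted over the list alone, with miR-20a at 4.63 ± 0.52 and miR-106a at 3.92 ± 0.48 (list adjusted p = 4.98e-09, and 0.0102 with an estimated correlation). Of the microRNAs linked to invasion 6 of 10 rose, and 6 adjusted over the list alone, with miR-107 at 3.51 ± 0.44 and miR-103 at 3.75 ± 0.66 (list adjusted p = 5.39e-06, and 0.0226 with an estimated correlation). Of the study's 6 microRNAs 1 rose, miR-21, and 3 adjusted over the list alone, which is not independent evidence (list adjusted p = 0.00826; adjusted p = 0.132 with an estimated correlation). miR-10a differed by 1.05 (adjusted p = 0.0758), miR-10b by 1.51, miR-27a by 2.24 (adjusted p = 0.0996), miR-155 by 0.37 and miR-373 by -0.46.

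Of the list members counted between the cell lines, miR-9 and miR-222 lost their calls on leaving out any of the 4 arrays, with adjusted p up to 0.189 without replicate 1 and 0.227 without replicate 2 of the MCF10A cells. miR-29b lost its call without replicate 1 of the MCF10A cells (0.0695) or replicate 2 of the MDA-MB-231 cells (0.0536), and miR-27b and miR-106b without the latter (0.0556 and 0.0561). Between the cell lines 166 probes were called, 73 higher and 93 lower in MDA-MB-231, and 569 in a fit of the cell arrays alone (202 higher and 367 lower), which had the smaller spread. The count was 82 and 92 without replicate 1 or 2 of the MCF10A cells, and 86 and 74 without replicate 1 or 2 of the MDA-MB-231 cells.

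**Figure D2:**
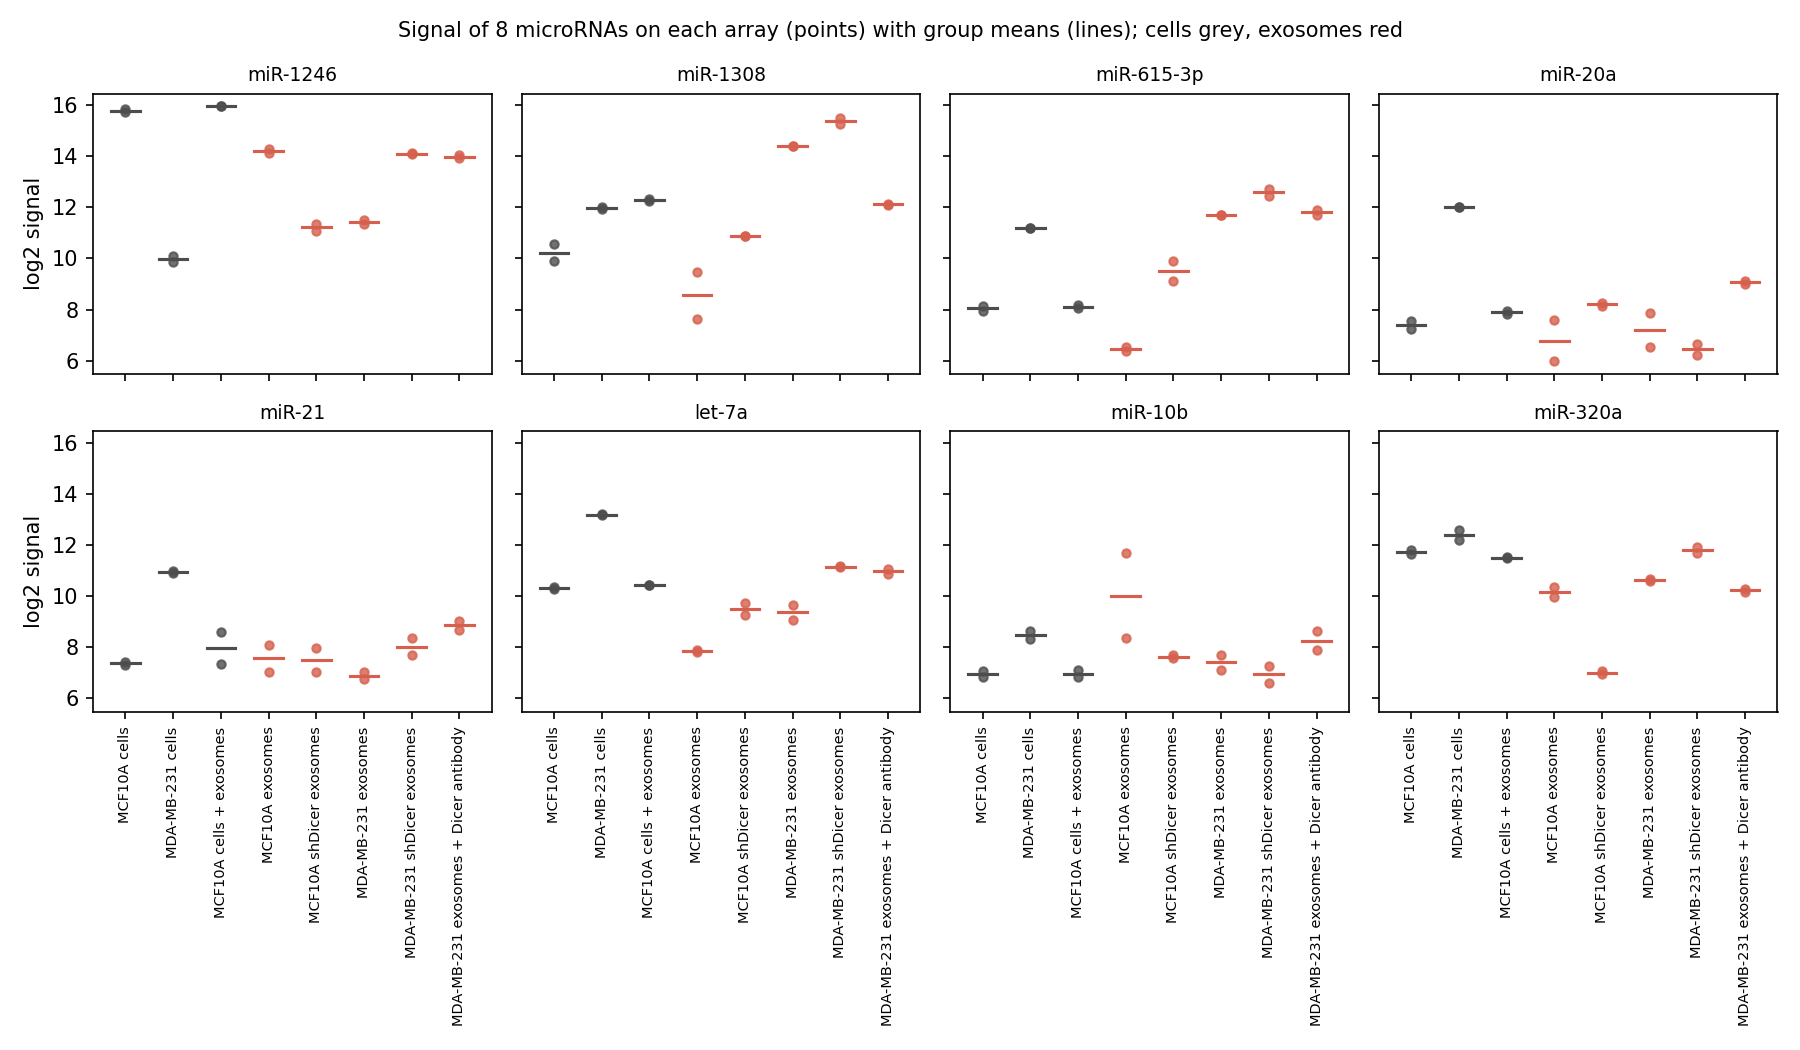
Log2 signal of 8 microRNAs in the 8 groups, with points for single arrays, horizontal lines for group means, cells in grey and exosomes in red. miR-1246 stood at 15.79 in MCF10A cells and 9.99 in MDA-MB-231 cells, and at 14.20 and 11.43 in their exosomes.

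To ask whether recipient cells change, MCF10A cells given MDA-MB-231 exosomes were compared with MCF10A cells without them. No group is labelled as given a vehicle or MCF10A exosomes. Effects of the procedure, and RNA of exosomes that stayed with the cells, therefore cannot be told apart from a response of the cells. miR-193a-5p was higher in the recipient cells by 2.05 ± 0.32 (12.89 against 10.84, n = 2 arrays each, adjusted p = 0.0177), miR-2861 by 2.31 ± 0.46 (adjusted p = 0.0336) and miR-29a by 1.59 ± 0.28 (adjusted p = 0.0336). miR-1250 was lower by -2.15 ± 0.28 (adjusted p = 0.0146), miR-1274b by -2.63 ± 0.39 (adjusted p = 0.0146), miR-607 by -3.11 ± 0.51 (adjusted p = 0.025) and miR-423-5p by -1.56 ± 0.30. None of the study's 6 microRNAs was called, over all probes or adjusted over the list alone: miR-21 differed by 0.60, miR-27a by 0.29, miR-10a by 0.06, miR-10b by 0.01, miR-373 by -0.38 and miR-155 by -0.80 (adjusted p = 0.286). That list's adjusted p was 0.896.

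In recipient cells the miR-23/27/24 list was higher with 1 of 5 members called, miR-23a at 1.34 ± 0.27, and 3 adjusted over the list alone (list adjusted p = 0.00479; adjusted p = 0.0829 with an estimated correlation). miR-24 differed by 1.40 ± 0.39 (adjusted p = 0.109). The miR-29 and miR-30 list was higher with 1 of 7 called, miR-29a, and 1 adjusted over the list alone (list adjusted p = 0.00102; adjusted p = 0.0732 with an estimated correlation). Among 14 microRNAs that bypass Drosha, the enzyme that normally frees precursors, 1 rose, miR-1226 by 1.26 ± 0.26, and 2 adjusted over the list alone; miR-1236 differed by 1.21 ± 0.29 (list adjusted p = 0.00277; adjusted p = 0.0655 with an estimated correlation). The let-7 list was lower by a median of -0.66 with 0 of 9 members called, over all probes or adjusted over the list alone (list adjusted p = 0.019; adjusted p = 0.362 with an estimated correlation). let-7i differed by -0.85 and let-7b by -0.75.

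In recipient cells 25 probes were called, 16 higher and 9 lower, and 315 in a fit of the cell arrays alone (146 higher and 169 lower). Every call of a named microRNA was lost on leaving out some array: 2 probes, miR-1250 and miR-208a-P, the latter singled out after its values were seen, were called without replicate 1 of the untreated cells. limma called 0 without their replicate 2 (127 at an unadjusted p under 0.05), 0 without replicate 1 of the treated cells (125) and 0 without their replicate 2 (112). Centring, which shifted the median of all probes by 0.11, left 8 calls and moved the higher share from 64% to 50%.

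The change in recipient cells was set against the difference between MDA-MB-231 and MCF10A exosomes, which shares no array with it. This asks whether microRNAs richer in MDA-MB-231 than in MCF10A exosomes rose in the recipients. It does not test those richer in the added exosomes than in the recipient cells themselves, so it cannot decide whether cargo was transferred. Across 1741 probes, which are not independent replicates, Pearson's r was 0.0726 and Spearman's rho 0.0300. Among the 98 probes higher in MDA-MB-231 exosomes, 56 were higher and 42 lower in recipient cells, with 1 called higher and 2 called lower and a median of 0.14 against -0.05 for all probes (camera p = 0.0206, and p = 0.0125 with an estimated correlation). In the fit of cell arrays these p-values were 0.0201 and 0.119. Among the 32 probes lower in MDA-MB-231 exosomes, 12 were higher and 20 lower in recipient cells (camera, limma's test of these probes against the others with preset correlation, n = 32 probes, p = 0.125). Recipient cells correlated with MDA-MB-231 exosomes at a mean r of 0.779, against 0.714 for untreated MCF10A cells. With MCF10A exosomes, which were not added, the values were 0.638 and 0.583, so the closeness was not particular to the added exosomes.

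The part of Dicer was addressed first with exosomes of shDicer cells. No group is labelled as having a control hairpin or a control antibody. Effects of either procedure therefore cannot be told apart from those of Dicer. In MDA-MB-231, miR-1246 was higher in shDicer exosomes by 2.68 ± 0.27 (14.11 against 11.43, n = 2 arrays each, adjusted p = 0.001). miR-363* rose by 3.05 ± 0.49 (adjusted p = 0.0199), miR-4299 by 2.51 ± 0.38 (adjusted p = 0.0195), let-7a by 1.78 ± 0.30 (adjusted p = 0.0201) and miR-361-5p by 1.74 ± 0.31 (adjusted p = 0.0298). The precursor probe of miR-1294 fell by 2.29 (SE 0.39, adjusted p = 0.0201). Not past the threshold were miR-181a* at -1.26, miR-148b* at -1.62 and the precursor probe of miR-3149 at -1.19 (each adjusted p = 0.0897), and miR-548c-5p at -1.17 (adjusted p = 0.131). In the let-7 list 1 of 9 members rose, let-7a, and 2 adjusted over the list alone, with let-7c at 1.34 ± 0.35 (list adjusted p = 0.0349, and 0.0527 in the fit of exosome arrays; adjusted p = 0.411 with an estimated correlation). Of 12 microRNAs reported in vesicles 1 rose, miR-1246, and 3 adjusted over the list alone; miR-223 differed by 1.98 ± 0.44 and miR-320a by 1.18 ± 0.28 (list adjusted p = 0.0326; adjusted p = 0.132 with an estimated correlation). None of the study's 6 was called over all probes or adjusted over the list alone: miR-21 differed by 1.13 (adjusted p = 0.361), miR-27a by 0.26, miR-10a by -0.10, miR-155 by -0.26, miR-10b by -0.47 and miR-373 by -0.88, with a list adjusted p of 0.934.

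In MDA-MB-231 shDicer exosomes 14 probes were called, 13 higher and 1 lower. limma called 0 in a fit of the exosome arrays alone (119 at an unadjusted p under 0.05) and 0 with only the arrays compared (188). On leaving out an array miR-1246 kept its call, alone without replicate 1 or 2 of the MDA-MB-231 exosomes or replicate 2 of the shDicer exosomes, and with miR-1294-P and miR-1179-P, the latter singled out after its values were seen, without replicate 1 of the shDicer exosomes. The other named microRNAs lost theirs in some of these fits, let-7a in all 4 (adjusted p = 0.115 and 0.0682 without replicate 1 or 2 of the MDA-MB-231 exosomes, 0.106 and 0.17 without replicate 1 or 2 of the shDicer exosomes). Centring shifted the median of all probes by 0.12.

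In MCF10A, by contrast, miR-1246 was lower in shDicer exosomes by -2.98 ± 0.27 (11.22 against 14.20, n = 2 arrays each, adjusted p = 7.96e-05). miR-221, reported to favour invasion, was lower by -4.01 ± 0.37 (adjusted p = 7.96e-05), miR-320a by -3.16 ± 0.28 (adjusted p = 7.96e-05) and miR-923 by -2.82 ± 0.25 (adjusted p = 7.96e-05). miR-320a is made without Drosha but cut by Dicer. mir-1910 was higher by 3.17 ± 0.27 (adjusted p = 7.96e-05), although its precursor probe was lower, and miR-615-3p by 3.04 ± 0.31 (adjusted p = 0.000159). Of the microRNAs reported in vesicles 3 of 12 fell, with miR-320d at -3.26 ± 0.52 (adjusted p = 0.104 in the fit of exosome arrays) besides miR-1246 and miR-320a, which kept their calls there, and adjusted over the list alone 1 rose and 5 fell (list adjusted p = 0.013; adjusted p = 0.103 with an estimated correlation). Of the microRNAs linked to invasion 3 of 10 fell, and 4 adjusted over the list alone (list adjusted p = 0.0428; adjusted p = 0.178 with an estimated correlation). Besides miR-221 these were miR-222 at -2.52 ± 0.44 and miR-107 at -2.42 ± 0.44, whose adjusted p became 0.0505 and 0.0583 without replicate 1 of the shDicer exosomes, and 0.129 and 0.132 in the fit of exosome arrays; the list itself had an adjusted p of 0.0527 there. None of the study's 6 was called over all probes or adjusted over the list alone: miR-10b differed by -2.39 (adjusted p = 0.113), miR-27a by -1.39, miR-373 by -0.26, miR-21 by -0.06, miR-10a by 0.16 and miR-155 by 0.20, with a list adjusted p of 0.581. In total 82 probes were called, 44 higher and 38 lower. A fit of the exosome arrays alone called 10 (2 higher and 8 lower), and limma with only the arrays compared called 0 (128 at an unadjusted p under 0.05). The count was 242 without replicate 1 of the MCF10A exosomes and 43 without replicate 1 of the shDicer exosomes.

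The change with shDicer was compared between the lines directly. miR-1246 differed by 5.66 ± 0.38 (MDA-MB-231 minus MCF10A, n = 2 arrays in each of 4 groups, adjusted p = 1.44e-05) and miR-320a by 4.34 ± 0.40 (adjusted p = 0.000228). The change was lower in MDA-MB-231 for miR-367 by -3.24 ± 0.50, miR-1294 by -3.42 ± 0.57 and mir-1910 by -3.16 ± 0.39. Among the microRNAs reported in vesicles 3 of 12 were higher in this contrast, miR-1246, miR-320a and miR-320d, and 4 adjusted over the list alone (list adjusted p = 0.00157; adjusted p = 0.0582 with an estimated correlation). For miR-320d at 3.80 ± 0.73 the call was lost without replicate 2 of the MDA-MB-231 exosomes (adjusted p = 0.0726) and without replicate 1 or 2 of the MDA-MB-231 shDicer exosomes (0.0512 and 0.0801). None of the study's 6 was called over all probes or adjusted over the list alone, with miR-10b at 1.92, miR-27a at 1.64, miR-21 at 1.19, miR-10a at -0.26, miR-155 at -0.46 and miR-373 at -0.62 (list adjusted p = 0.702). The contrast called 45 probes, 29 higher and 16 lower, and in the fit of exosome arrays 2, miR-1246 and miR-320a. The count was 188 and 71 without replicate 1 or 2 of the MCF10A exosomes, 23 without replicate 2 of the MDA-MB-231 exosomes, and 20 and 26 without replicate 1 or 2 of the MDA-MB-231 shDicer exosomes. Centring shifted the median of all probes by 0.12 and moved the higher share from 64.4% to 80%.

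Dicer inside exosomes was addressed with an antibody to it. Without a control antibody, effects of putting an antibody into exosomes cannot be told apart from those on Dicer. In MDA-MB-231 exosomes with the antibody, miR-223, a microRNA of myeloid cells, was higher by 3.12 ± 0.44 (9.35 against 6.23, n = 2 arrays each, adjusted p = 0.00373), miR-1246 by 2.56 ± 0.27 (13.98 against 11.43, adjusted p = 0.00162) and miR-361-5p by 2.34 ± 0.31 (adjusted p = 0.00324). miR-3197 was lower by -3.39 ± 0.43 (adjusted p = 0.00324) and mir-1913 by -2.58 ± 0.37 (adjusted p = 0.00373). The precursor probes of miR-1273d, miR-4294 and miR-1268 were lower by -4.41 ± 0.54, -2.91 ± 0.40 and -2.79 ± 0.37. miR-24 was higher by 2.45 ± 0.39 (adjusted p = 0.0063, and 0.0658 without replicate 1 of the MDA-MB-231 exosomes). All of the study's 6 microRNAs were higher, none of them called: miR-21 by 1.98 ± 0.50 (adjusted p = 0.0557), miR-373 by 0.86, miR-10b by 0.85, miR-155 by 0.63, miR-10a by 0.49 and miR-27a by 0.14. Adjusted over the list alone 1 rose, which is not independent evidence, and the list's adjusted p was 0.0796.

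With the antibody, the miR-17-92 list was higher with 1 of 13 members called, miR-25 at 1.81 ± 0.37, and 4 adjusted over the list alone (list adjusted p = 0.0344, and 0.0518 in the fit of exosome arrays; adjusted p = 0.132 with an estimated correlation). The microRNAs linked to invasion were higher with 1 of 10 called, miR-221 at 1.63 ± 0.37, and 4 adjusted over the list alone (list adjusted p = 0.0248; adjusted p = 0.142 with an estimated correlation). Those reported in vesicles were higher with 2 of 12 called, miR-1246 and miR-223, and 2 adjusted over the list alone (list adjusted p = 0.043, and 0.0527 in the fit of exosome arrays; adjusted p = 0.143 with an estimated correlation). The calls of miR-25 and miR-221 were lost on leaving out any of the 4 arrays, with adjusted p up to 0.15 without replicate 1 and 0.174 without replicate 2 of the MDA-MB-231 exosomes. In total 58 probes were called, 21 higher and 37 lower. limma called 0 in a fit of the exosome arrays alone (183 at an unadjusted p under 0.05) and 0 with only the arrays compared (177). The count was 17 and 28 without replicate 1 or 2 of the MDA-MB-231 exosomes and 27 without replicate 2 of the exosomes with antibody. Centring shifted the median of all probes by 0.17.

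Both MDA-MB-231 treatments were compared with the same 2 exosome arrays. Of their calls 6 higher probes were shared, against 0.157 for independent lists and 0 in 50 simulations of unchanged groups against those arrays, and 1 lower probe, against 0.0213 and 0. Across probes the treatments correlated at r = 0.298, against 0.522 for the simulated unchanged groups, and their covariance was 0.190 against 0.166. In a test added after the overlap was seen, each treatment was set against 1 of the 2 control arrays, so that none was shared. The correlation was then -0.0396 or -0.0127, depending on which array served which treatment, and in both cases miR-1246 was higher with both treatments. With 1 control array too few probes could be called with shDicer for the overlap of calls to be judged, so no conclusion is drawn from it.

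**Figure D3:**
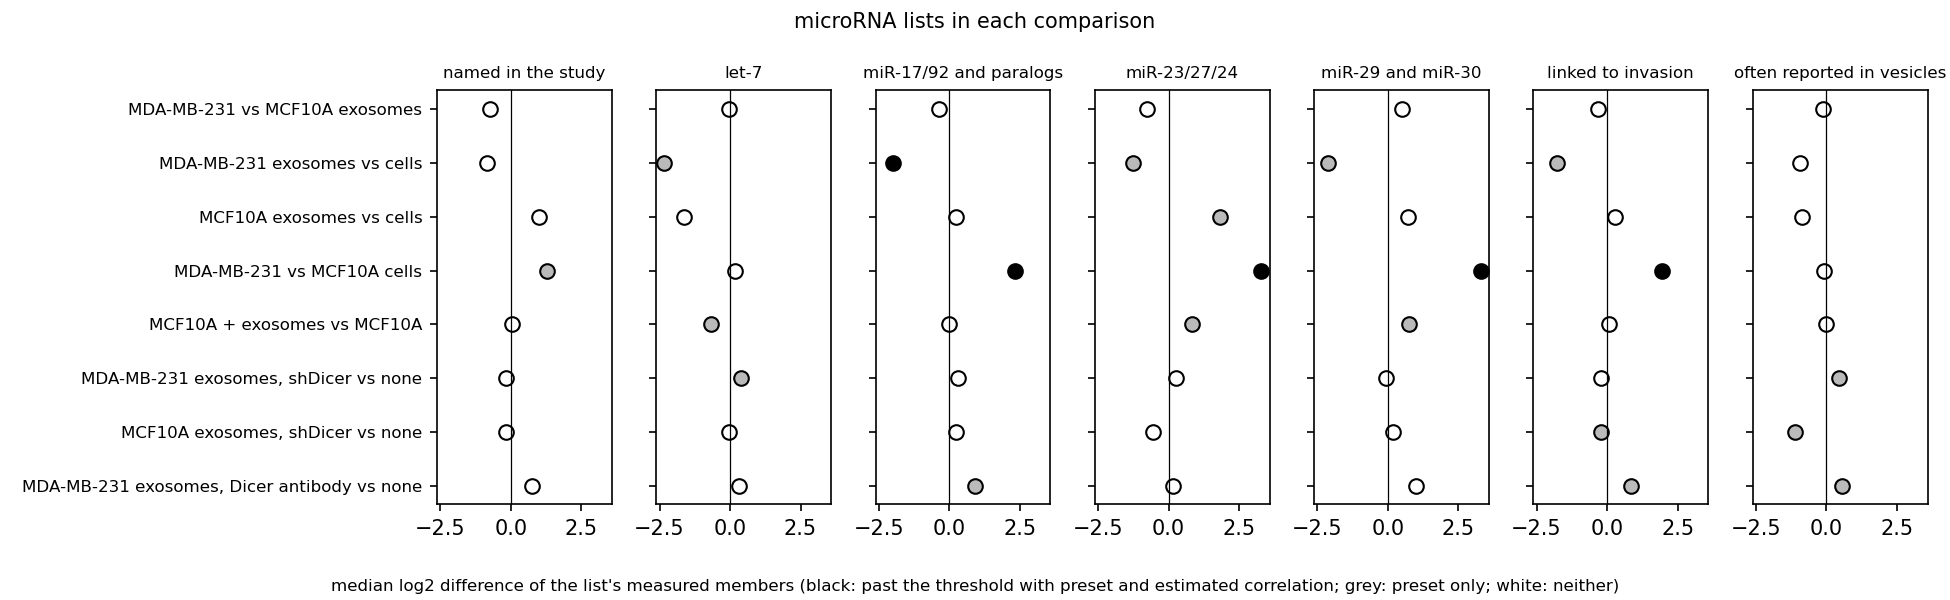
Median log2 difference of 7 microRNA lists in 8 comparisons, on a horizontal axis in log2 units; black points passed the list test with the preset and the estimated correlation, grey points with the preset correlation alone and white points with neither. The miR-17-92 median was -2.00 for MDA-MB-231 exosomes against cells and 2.35 for MDA-MB-231 against MCF10A cells.

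Since Dicer turns precursors into mature microRNAs, the 605 precursor probes were compared with the 1115 mature probes. The mature sequence lies within the precursor, so a mature probe can bind both and the classes need not separate the forms. On exosome arrays at most 38.3% of mature probes lay above the random-sequence probes. The differences below therefore cannot decide whether Dicer's cutting of precursors changed. The precursor median minus the mature median was 0.10 for MDA-MB-231 exosomes against cells (adjusted p = 0.365 in camera) and -0.08 for MCF10A exosomes against cells (adjusted p = 0.595). It was -0.08 in MDA-MB-231 shDicer exosomes, 0.18 in MCF10A shDicer exosomes and -0.10 with the Dicer antibody (each adjusted p = 0.441). For MDA-MB-231 exosomes against cells the difference was 0.215 and 0.153 without replicate 1 or 2 of the exosomes and 0.29 with dim probes filtered. It was -0.0300 in MDA-MB-231 shDicer exosomes without their replicate 1, -0.212 for MCF10A exosomes against cells without replicate 1 of the exosomes, and 0.0388 in MCF10A shDicer exosomes without their replicate 2. Without replicate 2 of the MCF10A exosomes the sign turned for both MCF10A comparisons, to 0.0338 for exosomes against cells and -0.0121 for shDicer. In the MDA-MB-231 exosomes with antibody 4 precursor probes rose and 13 fell, against 17 and 24 of the mature probes. Over 544 pairs of a precursor and a mature probe of the same name, the median of the pairs' differences was 0.19 for MDA-MB-231 exosomes against cells. For MCF10A exosomes against cells it was 0.07, opposite in sign to the difference of medians. It was -0.14 and 0.10 for shDicer in MDA-MB-231 and MCF10A, and -0.03 with the antibody.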

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

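The fits with array weights or of the same sample kind, and the tests of whether a single exosome group carried the spread, were chosen after the spread had been seen; the interactions were planned. The change from cells to exosomes differed between the lines by an interaction test, with 176 probes called. The difference was higher in MDA-MB-231 than in MCF10A for miR-1273d-P (8.55), mir-321-A (7.06), mir-566-P (6.47), miR-1273 (5.71) and mir-513c (5.48), and lower for miR-125b (-4.73), miR-106a (-4.35), miR-21 (-4.26), miR-1297 (-4.25) and miR-20a (-4.20). The call for mir-321-A was lost without replicate 1 or 2 of the MCF10A cells (adjusted p = 0.0704 and 0.0532). That for miR-1297 was lost without replicate 1 or 2 of the MCF10A cells (0.0762 and 0.0598), replicate 1 or 2 of the MDA-MB-231 cells (0.0704 and 0.0643) and replicate 1 of the MDA-MB-231 exosomes (0.0694). The count itself was 101 and 103 without replicate 1 or 2 of the MCF10A cells, 88 and 101 without replicate 1 or 2 of the MDA-MB-231 cells, and 267 without replicate 1 of the MCF10A exosomes.

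The change with shDicer also differed between the lines by an interaction test, with 45 probes called and 2 in a fit of the exosome arrays alone (miR-1246 and miR-320a). It was higher in MDA-MB-231 for miR-1246 (5.66), mir-204-P (5.35), miR-378c (4.37), miR-320a (4.34) and miR-4323 (4.15), and lower for miR-3117-P (-4.99), mir-568-P (-3.77), miR-1294 (-3.42), miR-367 (-3.24) and mir-1910 (-3.16). The call for miR-4323 was lost without replicate 2 of the MCF10A shDicer exosomes (adjusted p = 0.0669), replicate 2 of the MDA-MB-231 exosomes (0.0777) and replicate 1 or 2 of the MDA-MB-231 shDicer exosomes (0.082 and 0.0801). That for mir-568-P was lost without replicate 2 of the MCF10A exosomes (0.0691), replicate 1 or 2 of the MCF10A shDicer exosomes (0.0573 and 0.0811), replicate 2 of the MDA-MB-231 exosomes (0.0908) and replicate 1 of the MDA-MB-231 shDicer exosomes (0.0863). The count was 188 and 71 without replicate 1 or 2 of the MCF10A exosomes, 23 without replicate 2 of the MDA-MB-231 exosomes, and 20 and 26 without replicate 1 or 2 of the MDA-MB-231 shDicer exosomes.

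Probes outside the comparisons also carried signal. Of 490 mouse probes whose microRNA has no human namesake on the array, 34.2% lay above the random-sequence probes on exosome arrays and 51.3% on cell arrays. For the human mature probes these shares ran from 16.3% to 38.3% and from 34.3% to 44.8%. A signal above the random-sequence probes therefore does not show that the microRNA named was present. The median signal of a perfect-match probe minus that of its mismatch probes was -0.0371 on cell arrays and 0.118 on exosome arrays. Among microRNAs named here, miR-17 lay below its mismatch probes on cell arrays (-0.887, above all of them on 0 of 6 arrays) and miR-16 at their level (-0.0132, 0 of 6). miR-222 exceeded all of its mismatch probes on 2 of 6 cell arrays, miR-21 on 4, and miR-155 and miR-221 on 6. On the 10 exosome arrays the counts were 3 for miR-222, 3 for miR-21, 6 for miR-155, 4 for miR-221, and 1 each for miR-17 and miR-16. miR-221 differed from its mismatch probes by -2.00 in MCF10A shDicer exosomes, so its signal there is not shown to be specific.

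Replicate arrays of exosomes differed more than those of cells, and the counts above move with how that spread is modelled. Over all probes a single exosome group as the source is argued against, since the smallest exosome group SD was 1.73 times the largest cell group SD. Dim probes as the whole source stay open, since among probes with a mean signal above 10 the exosome spread was 1.41 times that of cells, between the values that would have decided it. For those bright probes a single group stays open too: without the MCF10A exosomes (SD 0.676) the ratio was 1.13, and the other exosome groups ran from 0.137 to 0.386 against 0.143 to 0.330 in cells. A lower signal over background on exosome arrays goes with the spread and could contribute, and the nature of the sample, exosome or cell, is the biological difference the design names and was not tested apart from it.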

How the results depend on the processing

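The fits with array weights, of the same sample kind, with any probe of a list member, and the estimated correlation for precursors were chosen after the data had been seen. Signal over background limits the exosome arrays, where at most 38.3% of mature probes exceeded the random-sequence probes, and 2 arrays per group limit every value. The fit of 16 arrays averages the spread of cells and exosomes. On simulated data with 1 spread for all probes of a group, its false share of calls was 28.9% between the exosomes of the lines (9.2% in the exosome fit). For MCF10A shDicer it was 37.9% (16.2%), and between the cell lines the fit recovered 1.19% of 1-unit changes (95.8% in the cell fit). Real probes differ in spread, so these shares need not hold for the data. Beyond this, the cause of the changes below was not tested. A change of scale of the values was not run, because the values were log2 already. No called direction of a named microRNA reversed. Of 175 calls of named microRNAs, 84 were lost with only the groups compared, 36 with array weights, 17 with centring, 6 with quantile normalization, 2 with trend and robust on, and 58 in fits of the same kind, where 63 were kept. The filter on dim probes lost none of the 152 it tested. Leaving out some array lost named calls in each comparison, and most of them in recipient cells, MDA-MB-231 shDicer exosomes and exosomes with the antibody.

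Counts of called probes follow in the order exosomes of the lines (130), cell lines (166), recipient cells (25), MDA-MB-231 shDicer (14), MCF10A shDicer (82), the difference between the lines in the shDicer change (45) and Dicer antibody (58), where they moved by over 1.5 times. With only the groups compared they were 0, 588, 265, 0, 0, 1 and 0 (limma; at an unadjusted p under 0.05 the zeros had 169, 188, 128 and 177). Fits of the same kind gave 31, 569, 315, 0, 10, 2 and 0. Array weights gave 40, 600 and 337 for the first comparisons, 10 for MCF10A shDicer, 6 for the difference and 20 for the antibody. The filter on dim probes gave 72 for recipient cells, 31 for MDA-MB-231 shDicer, 75 for the difference and 93 for the antibody. Trend and robust gave 88, 39 and 72 for recipient cells, MDA-MB-231 shDicer and the difference. Centring gave 8 for recipient cells and 34 for the antibody. The counts for exosomes against cells in either line, and their difference between the lines, stayed within 1.5 times outside the fits without an array.

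With the replicate number as a block the counts were 7 for recipient cells, 8 for MDA-MB-231 shDicer and 38 for the antibody, 21 of the 175 named calls were lost, and no other count moved by over 1.5 times. Same-numbered arrays did not deviate together (correlations -0.0449 to 0.0342 over 28 pairs of groups), so no pairing by number was seen. A weak effect of pairing could have been hidden by the spread between probes, so pairing is not excluded.

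Leaving out each array in turn gave 61 to 240 calls between the exosomes of the lines, 137 to 223 for MDA-MB-231 and 353 to 559 for MCF10A exosomes against cells, 88 to 267 for their difference, 74 to 92 between the cell lines, 0 to 2 in recipient cells, 1 to 3 for MDA-MB-231 shDicer, 43 to 242 for MCF10A shDicer, 20 to 188 for the shDicer difference and 17 to 54 for the antibody. The precursor minus mature median ran from 0.0912 to 0.215 and from -0.212 to 0.0338 (exosomes against cells in MDA-MB-231 and MCF10A), -0.104 to -0.0300 and -0.0121 to 0.176 (shDicer), and -0.100 to -0.0746 (antibody); without replicate 2 of the MCF10A exosomes it reversed, to 0.0338 and -0.0121. For MDA-MB-231 exosomes against cells it became 0.29 (unadjusted p = 0.036) with dim probes filtered, and at 0.10 had an unadjusted p of 0.026 with an estimated correlation, which did not pass after adjustment (adjusted p = 0.13). The correlation of recipient cells with exosome cargo ran from 0.0521 to 0.0810 and was 0.0187 with dim probes filtered. Of 170 list tests 28 were called, 9 with an estimated correlation, 23 with dim probes filtered and 22 with any probe of the member, of which 18 were shared. Of the 17 called within exosomes or within cells, 13 were called in fits of the same kind.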

Other observations

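The tests of carried-over RNA, scaling and names below were revised after a first value had been seen, the test of signal over background was added later and its criterion, which at first excluded that source, was revised once its value was seen, and both patterns were singled out after the results. Among lists without any called comparison, the miR-15/16 family had 4 of 7 members higher and 1 lower in MDA-MB-231 cells than in MCF10A cells (list adjusted p = 0.0791). miR-16 was higher by 2.88 ± 0.62 and miR-15b by 2.62 ± 0.64, whereas miR-497 was lower by -1.61 ± 0.31. The epithelial miR-200 group, which guards the epithelial state, had 1 of 7 members lower in MDA-MB-231 exosomes than in their cells, miR-200b at -1.91 ± 0.48 (list median -1.36, adjusted p = 0.0803). Between the exosomes of the lines miR-200b was lower by -1.82 ± 0.48 (adjusted p = 0.0441) and miR-429, of the same group, higher by 1.89 ± 0.52 (adjusted p = 0.048), and neither was called in the fit of exosome arrays (adjusted p = 0.187 and 0.222). The pluripotent stem cell clusters had 2 of 8 members higher in MDA-MB-231 exosomes than in cells, miR-371-3p at 1.88 ± 0.35 and miR-302a at 1.46 ± 0.37 (adjusted p = 0.0762).

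The lists of other sources gave no call in any comparison. The smallest adjusted p was 0.206 for blood and serum (Dicer antibody, 1 of 7 higher, miR-223), 0.219 for brain (MDA-MB-231 shDicer, 0 of 7 called in limma), 0.254 for muscle (difference between the lines in the shDicer change, 0 of 6 called), 0.0716 for the placental cluster (Dicer antibody, 1 of 35 higher, miR-518a-5p at 1.66 ± 0.39) and 0.343 for the imprinted cluster (exosome-cell difference between the lines, 0 of 42 called). For microRNAs reported to restrain tumours it was 0.254 between the cell lines, with 2 of 13 higher. The differences between the lines were weakly related in exosomes and in cells: across probes r was 0.0444 and rho -0.00504. In both, 16 probes were higher in MDA-MB-231, against 4.11 for independent lists, and 5 lower, against 1.71. These calls too come from 1 fit with a common spread per probe, so the counts for independent lists are not a fair reference.

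The profile of MDA-MB-231 shDicer exosomes shifted toward that of cells, with a slope of 0.162 on the cell-exosome difference measured in MCF10A, whereas the slope with the Dicer antibody was -0.112. Scaling between arrays stays open as a source. After quantile normalization the slope kept 0.957 of its size, which met the criterion set against scaling. The deposited distributions were already close, however, so that step could move the slope little and decides nothing. Centring cannot move a slope, and the authors' own normalization cannot be undone. Signal over background rose with the shift, to 36.9% and 38.3% of mature probes from 31.2% and 25.3%, and stays open: in MCF10A, where it rose to 25.2% and 24.2% from 16.3% and 18.7%, the slope of the shDicer change on the MDA-MB-231 axis was -0.0515 (-0.0744 to -0.0285 with each array left out), but those arrays did not reach the level of cell arrays. Cellular RNA carried into the preparation stays open too: the median shDicer change of the snoRNA probes higher in cells was -0.27 (SE 0.198, 3 probes), a value written beforehand as evidence against it, but all 3 lay below the 95th percentile of the random-sequence probes in exosomes and GAPDH was not higher in cells, so a small rise could not have been seen and that criterion was not used. The Dicer knockdown itself, the biological difference the design names, was not tested apart from these, nor from effects of the knockdown procedure, for which no control group exists.

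Probes whose microRNA name has no gene in the RefSeq table, among them miR-1308, miR-1274b, miR-1979 and miR-923, were more frequent among called probes: 42 of 704 probes called in any comparison between groups (5.97%) against 1.16% of uncalled probes. By comparison their share ran from 5.68% of calls for MDA-MB-231 exosomes against cells (Fisher's exact test over probes, adjusted p = 0.0103) to 16.9% between the exosomes of the lines (adjusted p = 2.38e-11), and it did not pass in recipient cells (2 of 25 calls, adjusted p = 0.18) or MDA-MB-231 shDicer exosomes (2 of 14, adjusted p = 0.0774). The 54 such probes carry only 28 names, and probes of 1 name are not independent, so these p-values tend to be too small. Brightness as the whole source stays open: draws matched on mean signal from all tested probes averaged 4.85% and reached 6.11%, and 4 of 1000 draws were as high as the share observed. Later draws from uncalled probes averaged 1.05% and reached 2.27%, but these are restricted by the outcome, so the criterion written beforehand, which they met, was not used; the brightest 10% of probes held 23 uncalled against 151 called. Some of these names may be fragments of other small RNAs and others were only renamed, such as miR-128a, which was not tested.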
